A study of Mus musculus with 4 samples.

How the data were processed

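The material was 4 single-cell RNA libraries (10x Genomics 3' v3 chemistry, per the labels' protocols), 1 for each combination of region (frontal cortex, midbrain) and genotype (transgenic, wildtype). The design text gives 3 mice per group, and the labels state that both regions came from the same group of 3 mice, but their mouse number is 3 for frontal cortex and 0 for midbrain, which was left unresolved. The cell tables name no mouse, so each group was treated as 1 sample, and the regions were deposited as 2 separate tables with both genotypes in each.

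The authors used Cell Ranger 3.0.0 and Seurat 3.1.5 with the mm10 genome, per the submitters' processing notes. The deposited matrices hold UMI counts per gene and cell, whole numbers with no scaling, for 19602 features in frontal cortex and 19956 in midbrain. The deposited cell tables also give each cell's mitochondrial share in percent, a cluster number and a cell type label. The cluster columns carry the names of an SCT assay and a nearest-neighbour graph at resolution 1, per the file headers. No header or label states which cells were filtered out or whether doublets were removed. Cluster and type assignments were taken as deposited: 24 clusters and 14 types in frontal cortex, 29 clusters and 15 types in midbrain, of which 4 and 6 clusters are astrocytes.

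The type labels were checked against 16 marker lists fixed before the data were examined. Some labels went against their leading genes, wholly or in part. OPC cells had 7 of 8 fibroblast markers highest in each region, though their leading genes in frontal cortex also held the OPC markers Pdgfra, Gpr17 and Lhfpl3. Frontal cortex CPC cells had 6 of 6 olfactory ensheathing markers highest, and midbrain imNeur cells 7 of 7 OPC markers. OLG cells were led by Prg4 and Slc47a1, with 1 of 8 oligodendrocyte markers highest in frontal cortex. Midbrain mNeur cells had 13 of 14 neuronal markers highest, with the hormone genes Cga and Tshb among their leading genes. These labels are therefore printed as deposited and no comparison of gene lists was made in them. No astrocyte cluster had more markers of another type than of its own among its 10 leading genes. In 5 of the 10 clusters (frontal cortex 1 and 22, midbrain 1, 3 and 5) these genes held no marker of any type, so the check says nothing there, and comparing astrocytes as a class rests on the authors' label.

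UMI counts were summed over the astrocytes of each library and scaled to CPM. The log2 ratio of 2 libraries has an exact 95% interval (Clopper-Pearson, conditional on the sum of both counts). With 1 library per group no test was run across cells and no p-value is given. Genes were counted as higher or lower at a log2 ratio of at least 0.58 in size (1.5 times) and 20 CPM in at least 1 library. A ratio against 0 UMIs was computed against a floor of 3 UMIs over the group, and its counting interval reaches below that value. The 34 gene lists were fixed before the data were examined. A list's median covers members with at least 20 UMIs over both libraries, and its place was read among 10000 random lists of the same size matched on expression in 20 bins, outside the 2.5th to 97.5th percentile counting as apart. This place describes these libraries and is not a test of genotype. A member was counted as higher or lower at 0.26 (1.2 times) with an interval that leaves out 0. Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs. Differences of cell type shares have Newcombe intervals.

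The genes named were fixed by rule: at 20 CPM and 100 UMIs in at least 1 library, the 10 largest and the 10 smallest ratios whose direction held under TMM scaling and the mean of per-cell CPM. Mitochondrial, ribosomal protein, haemoglobin and predicted genes, Xist, Tsix and Y-linked genes, and other cell types' markers in the fixed lists were left out. Other genes on chromosome X and genes of other types outside those lists, such as Gpr34, were not. Prnp, Gfap and 2 to 4 members of each list reported were added, 5 genes each way for the difference between regions, 10 each way between regions within a genotype, and up to 5 genes per cluster. The comparison of Gfap, Cd44, Serpina3n and the pan-reactive list between genotypes within clusters was added after the data were seen. Genes of close families whose reads may be split by the authors' counting, such as Serpina3n, Hist1h1e, Lyz2 and Hspa1a, are uncertain to that degree. Coordinates are from the GENCODE annotation of GRCm38, the assembly that mm10 names, and cover the whole gene, since the counts do not resolve exons. Some genes that the rule names, and part of the label check, are not reported here.

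The alternatives fixed before the data were examined were edgeR's TMM factors, DESeq2's size factors, a total without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, thinned cells, cells under 10% mitochondrial UMIs with at least 500 genes, clusters weighted alike, no filter on low genes, list members at 20 CPM, and own clusters. Added after the data were seen were cells under 5% mitochondrial UMIs, cells with at least 4 UMIs of another type's markers left out, and low-depth astrocyte clusters (median under 3000 UMIs in both libraries) left out. The rule on 4 UMIs used the markers of microglia, endothelial, mural, neuronal and oligodendrocyte types alone, each by itself. Under it erythroid genes stayed at 401 against 21.3 CPM in transgenic and wildtype frontal cortex astrocytes. No doublet caller was run, and the planned rule on 2 UMIs is described with the alternatives. Own clusters used 2000 variable genes, 30 components, 15 neighbours and Leiden resolutions of 0.3, 0.5 and 1. Their naming rule (at least 3 markers among the leading genes) left 1368 of 1932 cells of clusters that are mainly frontal cortex astrocytes unnamed at resolution 0.5, and was replaced, after that was seen, by the marker list with the highest mean relative level. Under the new rule 26 of these cells, and 471 of 4149 in midbrain, were not named astrocytes.

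The steps were tested on simulated counts drawn from the real means and depths with 200 changed genes. In frontal cortex (6904 genes) and midbrain (6930 genes) 100% of genes changed 2-fold and 100% of those changed 4-fold were found, 0 unchanged genes passed the size rule, and the intervals held the true ratio for 95.1% and 94.8% of genes. Unchanged lists stood apart in 2.94% and 3.24% of cases. The simulated counts were drawn independently for each gene, so this checks the calculations alone. It cannot show that the intervals or random ranges are wide enough for real counts, where UMIs gather in single cells and genes vary together. Precision follows depth: the astrocyte sums were 6981554 (transgenic) and 8495439 (wildtype) UMIs in frontal cortex, and 11520090 and 16467288 in midbrain. Intervals cover counting error alone, not differences between mice or preparations. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.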

Results

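Single-cell RNA sequencing (10x Genomics 3' chemistry) was carried out on cells dissociated from the frontal cortex and midbrain of transgenic mice, studied as a model of synucleinopathy, and of their wildtype littermates. The dissociation was aimed at glial and vascular cells of the adult brain. Each of the 4 groups (transgenic and wildtype frontal cortex, transgenic and wildtype midbrain) was 1 library. The design text gives 3 mice per group, while the mouse number in the sample labels is 3 for frontal cortex and 0 for midbrain. The frontal cortex libraries held 3775 transgenic and 6239 wildtype cells with 30712684 and 52849211 UMIs, and the midbrain libraries held 3995 and 7635 cells with 33168117 and 56588233 UMIs. Median UMIs per cell were 7515 and 7819 in frontal cortex and 8193 and 6900 in midbrain. The series is about astrocytes, so the comparisons below were made on the cells the authors labelled AC, here called astrocytes: 868 transgenic and 1067 wildtype in frontal cortex, 1512 and 2644 in midbrain. Among the 15 fixed astrocyte markers, 13 were highest in this label in frontal cortex and 10 in midbrain. Genotype and library coincided in each region, so each difference compares 2 libraries and has no replicate check. The 95% intervals given cover counting error alone, and levels are counts per 1000000 (CPM) of the summed astrocyte UMIs.

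Prnp, the prion protein gene (chromosome 2, 131909928 to 131938429, plus strand, GRCm38), was higher in transgenic astrocytes of both regions, with 1794 against 1232 CPM in frontal cortex (log2 ratio 0.54, 0.51 to 0.58) and 1778 against 1512 CPM in midbrain (0.23, 0.21 to 0.26). It was higher in the transgenic library in 14 of 14 labelled cell types of frontal cortex and 14 of 15 of midbrain. In CPM, the largest differences were in the cells labelled mNeur in frontal cortex (6010 against 308 CPM) and EPC in midbrain (6811 against 742 CPM).

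**Figure D1:**
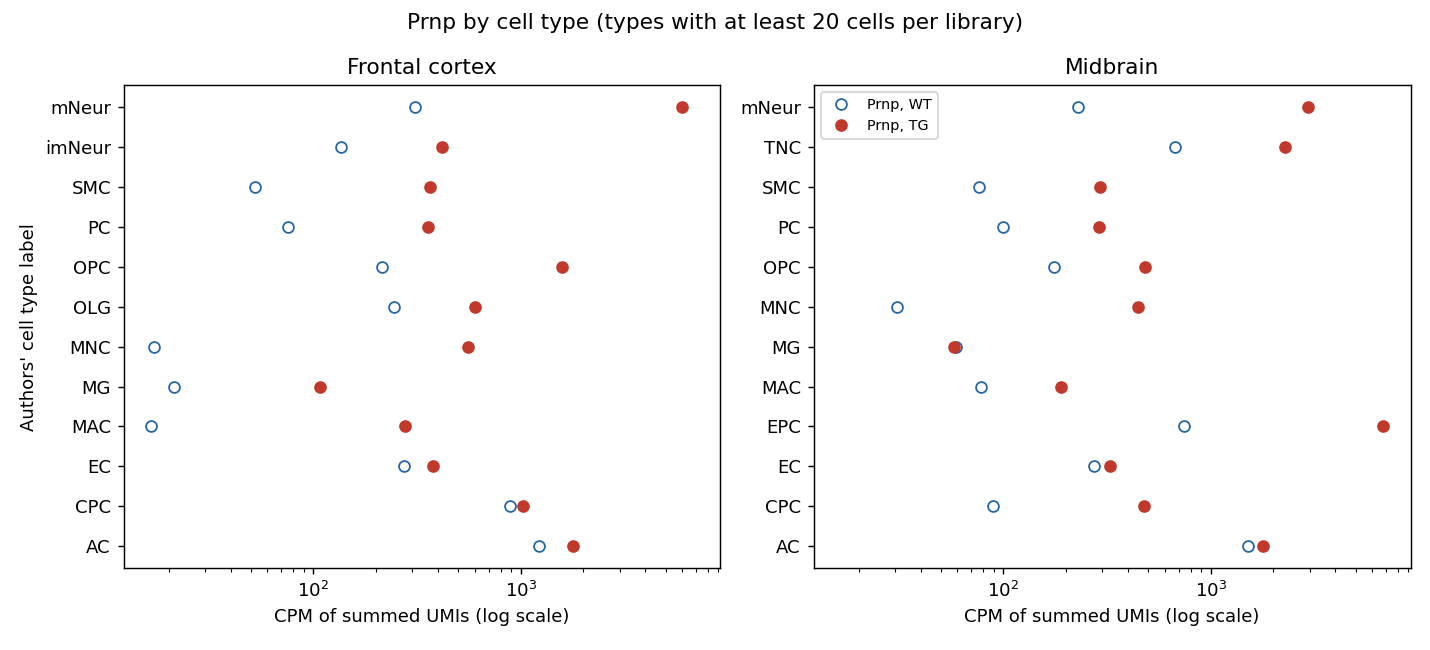
Prnp in wildtype cells (open circles) and transgenic cells (filled circles), in CPM on a log axis, for each of the authors' cell type labels with at least 20 cells per library in frontal cortex and midbrain. Prnp reached 6010 CPM in transgenic mNeur cells of frontal cortex and 6811 CPM in transgenic EPC cells of midbrain, against 308 and 742 CPM in wildtype.

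Cell type shares asked whether the 2 genotypes yielded the same mixture. Microglia (label MG) made up a larger share of the transgenic library in both regions, 38.3% against 30.6% in frontal cortex and 20.2% against 15.2% in midbrain. Endothelial cells (EC) made up a smaller share, 22.8% against 35.9% and 19.8% against 24.4%. The differences were 7.63 percentage points (5.71 to 9.56) and 5.01 points (3.54 to 6.50) for microglia, and -13.1 points (-14.9 to -11.3) and -4.54 points (-6.09 to -2.95) for endothelial cells. Astrocytes were 22.99% of transgenic and 17.1% of wildtype frontal cortex cells, a difference of 5.89 points that became -0.21 points when cells with at least 10% mitochondrial UMIs or under 500 genes were left out. In midbrain they were 37.8% and 34.6%, a difference of 3.22 points that became 1.40 points under the same filter. Shares depend on dissociation as well as on tissue, and 1 library per group gives no spread for them.

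Transgenic frontal cortex astrocytes carried much higher levels of genes of reactive astrocytes than wildtype ones. Gfap, the intermediate filament gene of reactive astrocytes (chromosome 11, 102887336 to 102900912, minus strand), was at 584 against 118 CPM (log2 ratio 2.31, 2.21 to 2.41). Serpina3n, a secreted protease inhibitor (chromosome 12, 104406729 to 104414329, plus strand), was at 46.6 against 1.77 CPM (4.72, 3.98 to 5.57). Cd44, the hyaluronan receptor (chromosome 2, 102811141 to 102901665, minus strand), was at 58.4 against 3.53 CPM (4.05, 3.51 to 4.64). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735, plus strand), had 156 transgenic and 0 wildtype UMIs, a log2 ratio of at least 5.98 against a floor of 3 UMIs (lower counting limit 5.67), with 43 of the 156 UMIs in 1 cell. Of 7120 genes at 20 CPM or more in either library, 263 were at least 1.5 times higher and 217 at least 1.5 times lower in transgenic astrocytes.

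The other genes with the largest excess included Ptx3, a pentraxin of innate immunity (36.1 against 1.41 CPM, log2 ratio 4.68), the sphingosine-1-phosphate receptor gene S1pr3 (37.8 against 2.001, 4.24) and the TWEAK receptor gene Tnfrsf12a (72.3 against 5.06, 3.84). Gap43, a growth cone protein gene, was at 26.4 against 3.06 CPM (3.11), and Bdnf, a neurotrophin gene, at 55.1 against 7.18 CPM (2.94). Lif, an IL-6 family cytokine gene, was at 21.6 against 2.94 CPM (2.88), with 50 of its 151 transgenic UMIs in 1 cell. The kinesin gene Kif5a was at 29.1 against 4.24 CPM (2.78). After each cell was thinned to 3000 UMIs, Gfap was found in 46.1% of transgenic and 15.2% of wildtype astrocytes, and in 6.95% and 0.94% of microglia, which should lack it. Without thinning the astrocyte shares were 62.1% and 26.1%, at median depths of 6638.5 and 7983 UMIs (7404 and 7373 in microglia), and thinning left out 233 transgenic and 200 wildtype astrocytes.

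Of the 34 gene lists, 12 had a median log2 ratio above the central 95% of random lists matched on expression, 3 lay below and 19 within. The pan-reactive list had a median of 2.31, with 9 of 11 members at least 1.2 times higher, and the A2 list, named after astrocytes following ischaemia, a median of 2.02 with 7 of 9 higher. Among their members were Osmr, the oncostatin M receptor gene (54.7 against 11.7 CPM, 2.23), S100a10 (158 against 35.5 CPM, 2.15), Emp1 (2.02) and the transcription factor gene Stat3 (1.21). The A1 list, named after astrocytes following inflammatory stimulation, had a median of 0.52 with 5 of 11 members higher (Gbp2 1.28, Fkbp5 1.03) and Srgn lower (-1.55). Genes of disease-associated astrocytes had a median of 0.49 with 12 of 20 higher, among them Vim (193 against 80.3 CPM, 1.26), the complement gene C4b (1.24) and Cd9 (0.90). NF-kB and cytokine signalling (median 0.36, 6 of 16 higher) was led by Bcl3 (3.91), Cebpd (1.93) and Socs3 (1.64). The interferon response list (0.36, 9 of 28 higher, 3 lower) held Oasl2 (1.82) and Irf9 (0.79) beside Ifi27l2a (-1.93).

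Among the other lists above the random range, all 13 mitochondrially encoded genes were higher (median 0.70), with mt-Cytb at 11470 against 5872 CPM. Heat shock and chaperone genes (0.26, 8 of 17 higher, 3 lower) ranged from Hspb6 (1.71) and Bag3 (1.41) to Hspa1a (-0.84). Non-telencephalic astrocyte genes had a median of 0.49 (4 of 6 higher, Sparc 0.88, Itih3 0.78). The medians of the unfolded protein response (0.18, Canx 0.52, Atf3 -1.33), glycolysis (0.17, Pfkfb3 0.74) and Parkinson disease genes (0.19, Uchl1 1.12) were small. The 19 lists within the range included glutamate uptake (0.05), cholesterol synthesis (-0.04), lysosome (0.01) and astrocyte identity (0.10).

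Immediate early genes, which neurons and glia switch on within minutes of a stimulus, were lower in transgenic frontal cortex astrocytes, with 20 of 21 members at least 1.2 times lower (median -1.10). Nr4a1 was at 12.9 against 41.4 CPM (-1.68), Btg2 at 39.4 against 133 CPM (-1.76) and Klf2, a flow-responsive transcription factor gene of endothelium, at 40.1 against 161 CPM (-2.01). In wildtype frontal cortex, Klf2 was at 4095 CPM in endothelial cells and Btg2 at 2430.5 CPM in microglia. The list's median lay within the random range when astrocytes with RNA of such types were left out, a cut that removed deeper cells more often, as given below. Thyroid hormone and circadian genes had a median of -0.21, with 8 of 21 lower and 5 higher, among them the clock gene Per1 (27.6 against 59.2 CPM, -1.10), Tsc22d3 (-0.76), Cry1 (0.74) and Hr (0.95). Telencephalic astrocyte genes had a median of -0.25 with 4 of 9 lower (Emx2 -0.91, Fezf2 -0.80). Myoc, the myocilin gene, was at 0.43 against 37.4 CPM (-6.44, -8.73 to -4.88), but 314 of its 318 wildtype UMIs came from 10 cells. Several of the lowest genes are microglial or endothelial, namely Lyz2 (-2.48, with 342 of 434 wildtype UMIs in 1 cell), Rgs1 (-1.83), Abcb1a (-1.68), Gpr34 (-1.59) and Hpgds (-1.58), and Ndrg1 (-1.64) was lower too.

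The frontal cortex astrocytes of the 2 genotypes also differed in quality and in RNA of other types. Median mitochondrial share was 9.68% in transgenic and 5.27% in wildtype astrocytes, and 17.6% and 46.1% of the cells were under 5%. Summed microglial markers were at 617 against 1228 CPM (log2 ratio -0.99), endothelial markers at 261 against 633 CPM (-1.28), neuronal markers at 138 against 53.8 CPM (1.36) and haemoglobin and other erythroid genes at 314 against 20.1 CPM (3.96). Cells with at least 4 UMIs of microglial, endothelial, mural, neuronal or oligodendrocyte markers were then left out. This kept 416 of 868 transgenic and 603 of 1067 wildtype astrocytes. They held 2172863 of 6981554 and 3756188 of 8495439 UMIs, so deeper cells were removed more often. The values that follow hold for these shallower cells. Their immediate early median was -0.07, within the random range. Lyz2, Rgs1 and Gpr34 changed sign (0.79, 0.038 and 0.35), and 512 genes were higher. Among cells under 5% mitochondrial UMIs, 708 genes were higher, 71.8% of those past the size rule against 54.8% of the main count (66.7% with mitochondrial and ribosomal protein genes left out of the total), and the A1 and NF-kB medians were -0.19 and -0.044. With the authors' clusters weighted alike, Gfap had a log2 ratio of 1.62, the A1 median was -0.020, and the telencephalic median of -0.15, the heat shock median of 0.14 and the glycolysis median of 0.05 lay within the random range. So did the A1 and interferon medians in thinned cells (0.27 and 0.30) and the unfolded protein response with the mean of per-cell CPM (0.13). The mitochondrially encoded genes also did among cells under 5% mitochondrial UMIs (0.07), but that filter caps these same genes, so this value says nothing about them.

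**Figure D2:**
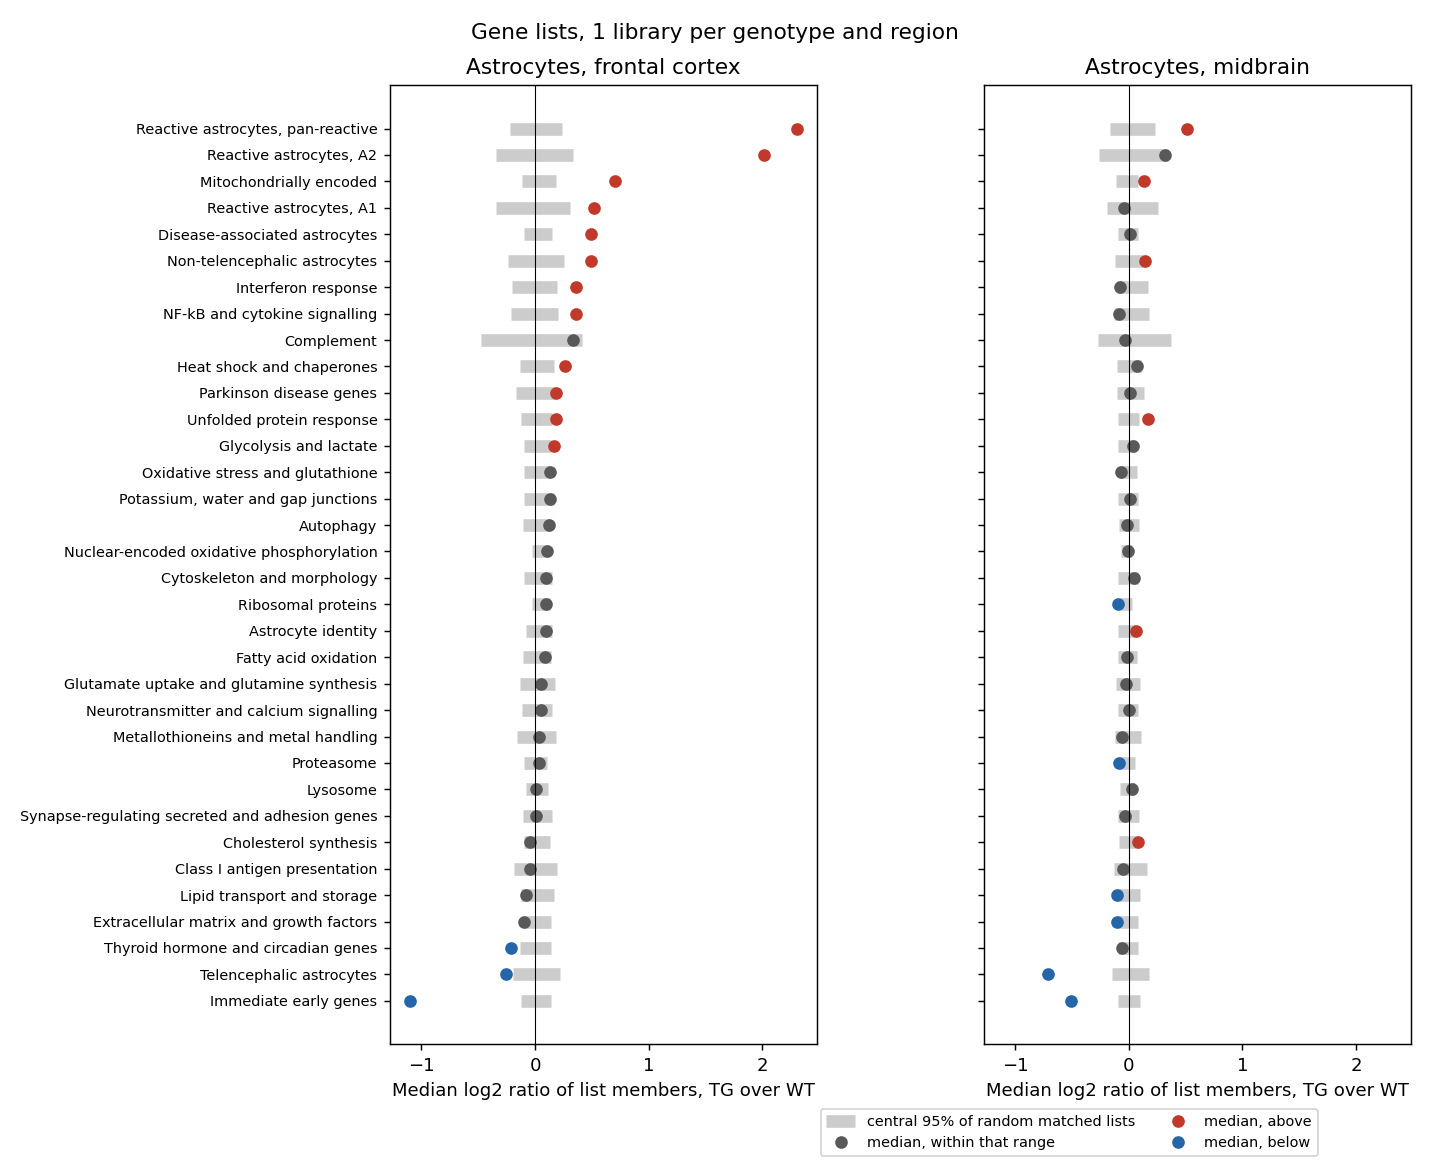
Median log2 ratio (transgenic over wildtype astrocytes) of each of the 34 gene lists in frontal cortex and midbrain, with grey bars for the central 95% of 10000 random lists matched on expression, red points above that range and blue points below it. The pan-reactive list stands at 2.31 in frontal cortex and 0.51 in midbrain, and immediate early genes at -1.10 and -0.51.

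In midbrain the same comparison gave smaller differences. Serpina3n was at 30.03 against 11.96 CPM (log2 ratio 1.33, 1.07 to 1.59), with 71 of its 346 transgenic UMIs in 1 cell, and Gfap at 206 against 144 CPM (0.51, 0.43 to 0.59). The 10 highest cells of each library held 1063 of the 2369 transgenic and 915 of the 2376 wildtype Gfap UMIs. Cdkn1a, the gene of the cell cycle inhibitor p21, was at 55.3 against 25.2 CPM (1.13) and the stress-responsive gene Nupr1 at 21.1 against 9.84 CPM (1.10). Egr1, an immediate early transcription factor gene, was lower, at 31.7 against 86.7 CPM (-1.45, -1.62 to -1.29), as was Id4, an inhibitor of bHLH transcription factors, at 186 against 334 CPM (-0.85). Of 7075 genes at 20 CPM or more, 59 were at least 1.5 times higher and 43 at least 1.5 times lower.

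The remaining genes named by size were Polr2l (0.95), Ccdc152 (0.92), Mtmr11 (0.92), Bdnf (0.87), Hr (0.86), Etv4 (84.1 against 46.5 CPM, 0.85) and Mitd1 (0.85) on the higher side. On the lower side were Myoc (15.3 against 33.8 CPM, -1.14, with 149 of 176 transgenic UMIs in 1 cell), Swap70 (-0.96), the homeobox gene Hopx (37.8 against 71.8 CPM, -0.92), Ier2 (-0.87), the histone gene Hist1h1e (-0.84), Dusp1 (-0.82), the taurine transporter gene Slc6a6 (-0.80) and Fos (80.8 against 140 CPM, -0.80). The pan-reactive list had a median of 0.51, with 6 of 11 members higher and 2 lower, among them Cd44 (2.57), S1pr3 (2.49), Timp1 (43 transgenic and 0 wildtype UMIs, at least 4.36 against that floor, lower limit 3.996) and Cxcl10 (-1.14). Immediate early genes were again lower (median -0.51, 15 of 21). Telencephalic astrocyte genes were lower in 6 of 9 members (median -0.72), among them Fezf2 (-1.61), Hopx (-0.92), and the forebrain transcription factor genes Lhx2 (-0.74) and Emx2 (-0.72). The unfolded protein response had a median of 0.17 (4 of 20 higher, 1 lower), with Sdf2l1 at 0.78, Atf4 at 0.35 and Atf3 at -0.61, and non-telencephalic genes a median of 0.14 (4 of 12 higher, 1 lower), with Irx3 at 0.44, Irx5 at 0.40 and En1 at -0.69.

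Of the 34 lists, 6 lay above the random range in midbrain, 6 below and 22 within. The others above were mitochondrially encoded genes (0.14), cholesterol synthesis (0.09, 5 of 24 members higher) and astrocyte identity (0.06, Sox9 0.43). The others below were lipid transport (-0.11), extracellular matrix and growth factors (-0.10, Id1 -0.66, Igfbp2 0.59), ribosomal proteins (-0.09) and proteasome (-0.08, with 0 of 30 members past 1.2 times). In midbrain astrocytes, choroid plexus markers, led by Ttr, were at 1947 against 3524 CPM (-0.86), erythroid genes at 260.5 against 47.0 CPM (2.47) and microglial markers at 307 against 278 CPM (0.14), and the median mitochondrial share was 7.07% against 6.54%. Among cells under 5% mitochondrial UMIs, the pan-reactive median was -0.15, the Gfap ratio 0.06 and the Serpina3n ratio 0.28, and with clusters weighted alike the telencephalic median was -0.27 and the Gfap ratio 0.18. Of the 12 lists outside the random range, the calls of 6 with medians of 0.14 or less in size (astrocyte identity, cholesterol synthesis, lipid transport, extracellular matrix, proteasome and non-telencephalic genes) were lost under at least 4 of the alternatives run.

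The authors' astrocyte clusters showed where the reactive genes differed. Cluster 1 held the most astrocytes in both frontal cortex libraries, 44.9% of the transgenic and 73.2% of the wildtype ones. Most of the others were in clusters 4 (35.6% against 19.2%) and 11 (13.4% against 3.19%), which Gfap helps define. In midbrain, cluster 1 held the most in the transgenic and cluster 3 in the wildtype library. In frontal cortex cluster 1, marked by Crym and Pfkfb4, Gfap was at 203 against 64.8 CPM (log2 ratio 1.65, 1.48 to 1.82) and the pan-reactive median was 1.14. In midbrain, cluster 10, marked by the telencephalic genes Fezf2, Lhx2 and Hopx and by Crym, had Gfap at 1041 against 180 CPM (2.53, 2.37 to 2.70), from 106 transgenic and 284 wildtype cells. Its pan-reactive median was 2.68 with 9 of 9 members above 0, Cd44 was at 69.8 against 1.79 CPM (5.29), and Serpina3n at 179 against 10.3 CPM (4.12), with 71 of its 202 transgenic UMIs in 1 cell. In midbrain cluster 1 (Acvr1c, Igfbp2, P2ry1, Pax3), cluster 3 (Cyp26b1, Pax3) and cluster 5 (Nkx6-2, Fbln5, Rhcg, Hhip) the Gfap ratios were -0.01, 0.23 and -0.24 and the pan-reactive medians -0.01, 0.07 and -0.26. Frontal cortex cluster 22, marked by Nkx6-2, Igsf1 and Gria1, had Gfap at 55.3 against 48.3 CPM (0.19, -0.77 to 1.19). Gfap was among the genes that define frontal cortex clusters 4 and 11 and midbrain clusters 4 and 22, so it was not compared between genotypes there. The pan-reactive list, which holds Gfap and other genes that mark these clusters, had medians of 3.04 and 3.14 in frontal cortex clusters 4 and 11. In midbrain cluster 4 it was -1.28, with 0 of 4 members above 0, at median depths of 1315 and 1343 UMIs per cell and with 204 of 370 transgenic Gfap UMIs in 1 cell. It had a median of 2.18 in midbrain cluster 22, which Lhx2, Hopx and Crym also mark. Frontal cortex cluster 4 and midbrain cluster 22 also had median depths under 3000 UMIs per cell.

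**Figure D3:**
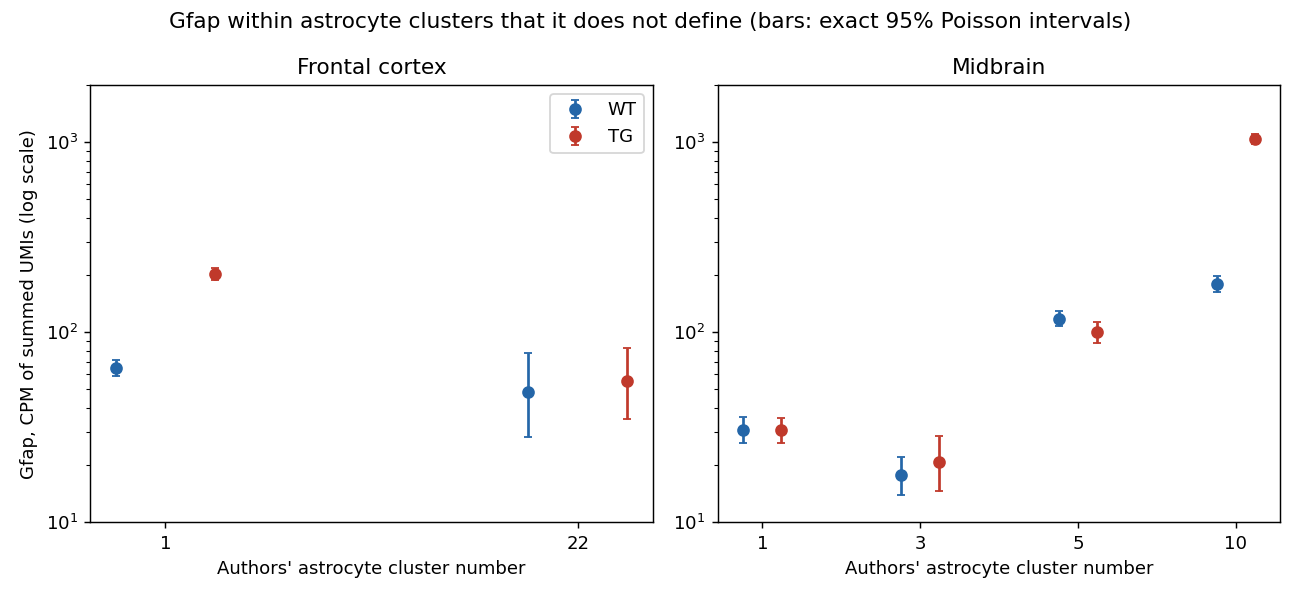
Gfap level (CPM, log axis, with exact 95% Poisson intervals) in wildtype (blue) and transgenic (red) cells of the astrocyte clusters that Gfap does not define, in frontal cortex (1 and 22) and midbrain (1, 3, 5 and 10). The genotypes stand apart in frontal cortex cluster 1 (203 against 64.8 CPM) and midbrain cluster 10 (1041 against 180 CPM).

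The difference between regions in the transgenic excess was taken as the midbrain minus the frontal cortex log2 ratio. Serpina3n (-3.39), the protease inhibitor gene A2m (-2.92), Tnfrsf12a (-2.61), Gap43 (-2.57) and the transcription factor gene Foxb1 (-2.35 against the floor of 3 UMIs, as frontal cortex wildtype astrocytes held 0) had the larger ratio in frontal cortex. Myoc (5.30), Lyz2 (2.34), Laptm5 (1.77), Gpr34 (1.62) and Fosb (1.61) had the larger ratio in midbrain, and each of these 5 was lower in transgenic frontal cortex astrocytes. Lyz2, Laptm5 and Gpr34 are genes of microglia and macrophages, and summed microglial markers had a log2 ratio of -0.99 in frontal cortex and 0.14 in midbrain astrocytes. By size, 262 genes had a ratio at least 1.5 times larger in frontal cortex and 249 in midbrain (160 with clusters weighted alike). Of the 263 genes higher in frontal cortex, 207 had a ratio above 0 in midbrain and 34 were at least 1.5 times higher there, while 1 was at least 1.5 times lower. Of the 217 lower in frontal cortex, 165 had a ratio below 0 in midbrain and 33 were at least 1.5 times lower, with 0 at least 1.5 times higher. The regional difference itself was not tested, since each group was 1 library.

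**Figure D4:**
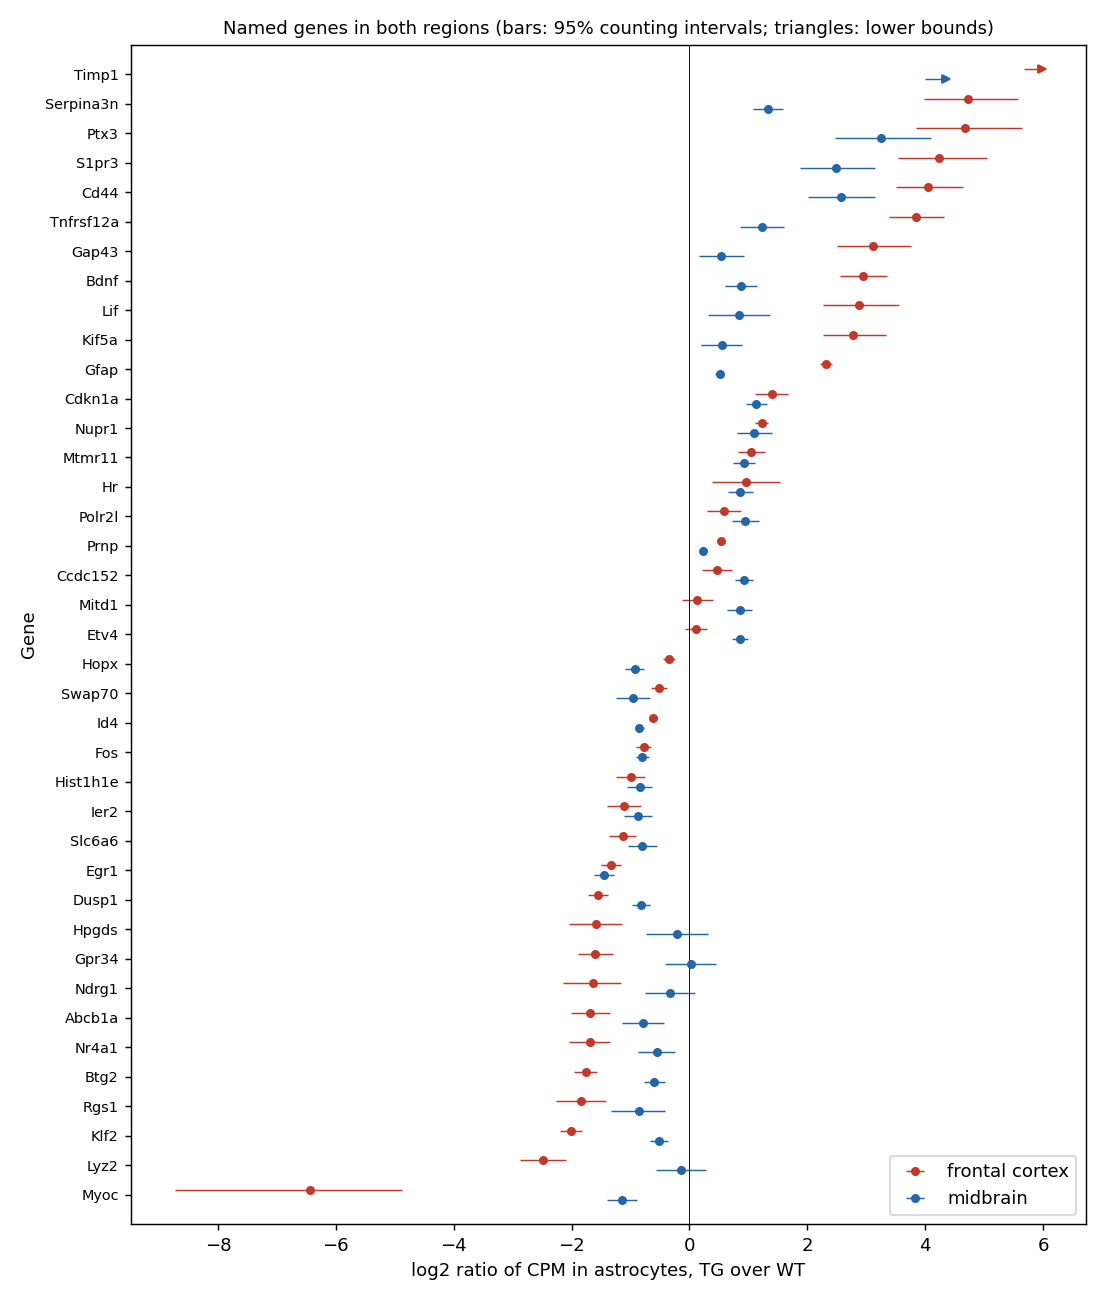
Log2 ratio (transgenic over wildtype astrocytes) with its 95% counting interval for the named genes in frontal cortex (red) and midbrain (blue), with a triangle where the value is a lower bound. Serpina3n is at 4.72 in frontal cortex and 1.33 in midbrain, and Gfap at 2.31 and 0.51.

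Midbrain and frontal cortex astrocytes were compared within each genotype to describe regional identity. In wildtype, the patterning genes Irx1 (27.0 against 0.12 CPM, log2 ratio 7.84, 5.35 to 13.15), Foxb1 (43.1 against 0, at least 6.93 against a floor of 3 UMIs, lower counting limit 6.63), Irx5 (40.6 against 0, at least 6.85 in the same way, lower limit 6.54) and Irx3 (5.87) were higher in midbrain, together with the angiotensinogen gene Agt (1528 against 82.6 CPM, 4.21), Igsf1 (167 against 5.06 CPM, 5.04), Gjc3 (4.97), Car14 (4.48), Hotairm1 (4.43) and Sfrp5 (3.95). Chrdl1, a BMP antagonist gene (3.95 against 122 CPM, -4.95), Lypd6 (-4.41), Adam23 (-3.79), the hepatocyte growth factor gene Hgf (-3.79), Ephb1 (-3.70), Nupr1 (9.84 against 127 CPM, -3.69), Lama3 (-3.66), Dmrta2 (-3.61), Tfcp2l1 (-3.60) and Me3 (-3.52) were higher in frontal cortex. Of 7193 genes, 474 were at least 1.5 times higher in midbrain and 515 in frontal cortex, and of these 460 and 503 had the same direction in transgenic astrocytes, where Lhx2 (20.9 against 266 CPM, -3.67) and Atp1b1 (38.3 against 426 CPM, -3.48) joined the largest. In transgenic astrocytes 628 of 7323 genes were higher in midbrain and 643 in frontal cortex.

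Telencephalic genes had a median log2 ratio of -2.002 in wildtype and -2.25 in transgenic astrocytes, with 7 of 9 higher in frontal cortex in each, and non-telencephalic genes medians of 3.41 and 3.09 with 8 of 8 higher in midbrain. Neurotransmitter and calcium signalling genes were higher in midbrain (0.58 and 0.59), among them the AMPA receptor gene Gria1 (302 against 43.1 CPM in wildtype, 2.81) and the GABA transporter gene Slc6a11 (2217 against 583 CPM, 1.93). Ribosomal protein genes (-0.42 and -0.53), cytoskeleton genes (-0.40 and -0.50, Ezr -2.21 in wildtype) and extracellular matrix genes (-0.56 and -0.52, with Hapln1 at -2.49 and Itih3 at 2.79 in wildtype) were higher in frontal cortex. The pan-reactive median was -0.44 between the wildtype libraries and -1.50 between the transgenic ones, where 9 of 11 members were higher in frontal cortex. Immediate early genes were higher in wildtype frontal cortex in 21 of 21 members (median -1.02) and in transgenic frontal cortex in 12 of 21 (-0.41). Wildtype frontal cortex astrocytes also held more microglial markers (1228 against 278 CPM in wildtype midbrain astrocytes) and endothelial markers (633 against 195 CPM). The regions were deposited as separate tables, so a difference between them also holds any difference in their preparation.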

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

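The tests on marker sums, on handling and on free RNA for Prnp were chosen after the result was seen, and the setting of cells under 5% mitochondrial UMIs was added after the data were seen.

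Prnp stood out in cells that no astrocyte comparison used. It was at 6010 CPM in transgenic and 308 CPM in wildtype cells labelled mNeur in frontal cortex, and at 6811 and 742 CPM in cells labelled EPC in midbrain. Free RNA alone would give every type a like excess, but the highest Prnp excess was 19.3 times the median over types in the region where that ratio was lower. The labels do not name the promoter of the transgene, so transcripts of the transgene counted as Prnp and a change in the mouse Prnp gene itself both stay open.

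Pan-reactive genes were higher in transgenic frontal cortex astrocytes, with a median log2 ratio of 2.31. A lower quality of the transgenic cells as the whole cause is argued against by a median of 3.05 among cells under 5% mitochondrial UMIs, and different cluster shares by a median of 2.18 with clusters weighted alike. RNA or cells of microglia, endothelium, mural cells or fibroblasts would raise the markers of these types, and the largest of their 4 ratios was -0.37. With cells holding at least 4 UMIs of another type left out, the microglial and mural ratios were 0.26 and 0.10. The endothelial and fibroblast ratios were then -0.05 and -0.84. Markers of some types outside these 4 were higher, such as neuronal (1.36) and erythroid (3.96) ones, and some were lower. The test left those types out and its sign changed with the cells used, so RNA of other types stays open. Handling or injury of the transgenic tissue cannot be told apart from genotype with 1 library per group. A response to the transgene therefore stays open as a hypothesis beside it.

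Telencephalic astrocyte genes were lower in transgenic midbrain astrocytes, with a median log2 ratio of -0.72. Fewer astrocytes of telencephalic character in the transgenic library may account for part of it: the 50 genes highest in wildtype frontal cortex against midbrain had a median of -0.21 in midbrain, below the random range. Lower levels of such genes within cells would give the same sign, so this value cannot tell fewer such cells from a change within cells. Different shares of the authors' clusters cannot be told apart from a change within cells, since the list's median with clusters weighted alike was -0.27, closer to the bound of -0.26 than the random spread. The bound's margin was applied after this value was seen. An effect of genotype on these genes stays open, as does the exact tissue dissected for each library.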

How the results depend on the processing

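Tests added after the data were seen were cells under 5% mitochondrial UMIs, cells with at least 4 UMIs of another type left out, and low-depth clusters left out. Of 86 counts under alternatives, 73 stayed within 1.5 times. Of 459 values of named genes, 359 stayed within their interval, 97 moved and 3 changed sign. Of 737 list medians, 632 kept their call, 44 gained one, 57 lost one and 4 changed sign. The cause was not tested for any of the following.

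Thinned cells gave 472 higher genes in frontal cortex and 100 in midbrain. With no filter on low genes these were 1033 higher and 1135 lower in frontal cortex and 794 and 581 in midbrain, as that setting counts more genes. With clusters weighted alike, frontal cortex had 143 lower genes and an A1 median of -0.020, and 160 genes (249 as reported) had the larger ratio in midbrain. Cells under 5% mitochondrial UMIs gave 708 higher genes in frontal cortex and 186 higher and 115 lower in midbrain, 7 midbrain lists standing apart in place of 12, A1 and NF-kB medians of -0.19 and -0.044 in frontal cortex and a pan-reactive median of -0.15 in midbrain. Leaving out cells with at least 4 UMIs of another type gave 512 higher genes in frontal cortex, with Lyz2 at 0.79, Rgs1 at 0.038 and Gpr34 at 0.35. That setting removed deeper cells more often. It also selects on the markers themselves: their ratios became 0.26 (microglia), -0.064 (oligodendrocytes) and 0.10 (mural) in frontal cortex and -0.15 (microglia) in midbrain. Under 10% mitochondrial UMIs with at least 500 genes, share differences were -0.21 points for astrocytes, 10.8 for microglia and -10.9 for endothelial cells in frontal cortex, and 6.55 for microglia in midbrain.

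The planned rule on 2 UMIs of another type left 28 transgenic and 73 wildtype frontal cortex astrocytes and 3 and 2 in midbrain, and gave no usable value. No paired analysis was possible because the cell tables name no mice and no test was made, so the alternatives by mouse were not run. Depth limits genes found with few UMIs most, such as Timp1 with 43 transgenic and 0 wildtype UMIs in midbrain.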

Other observations

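The genes named by size in microglia and endothelial cells passed a filter on their own type's level that was chosen after the data were seen. Members named from the gene lists did not have to pass it, and some were higher in another type. Oasl2, for example, was at 14.5 CPM in transgenic frontal cortex microglia and 117 CPM in endothelial cells of that library. The test of cluster 10 was written before its result.

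Microglia and endothelial cells differed between genotypes as well. In frontal cortex microglia, the chemokine genes Ccl5 (39.2 against 2.46 CPM, log2 ratio 3.996) and Ccl12 (545 against 155 CPM, 1.82) and the Fc receptor gene Fcgr4 (1.60) were higher in the transgenic library. Ccl5 was also a leading gene of frontal cortex MNC cells, which had 7 of 7 T and NK cell markers highest. Whether cells or RNA of that type supplied the Ccl5 UMIs in microglia was not tested. Interferon response genes in frontal cortex microglia had a median of 0.50, above the random range, with Ifi27l2a at 1.996, Oasl2 at 1.73, Irf7 at 1.70 and Isg15 at 0.96. In midbrain microglia the interferon median was -0.23, below the range. Lying outside the range was common in microglia: in frontal cortex 20 of 34 lists lay above it and 4 below, and in midbrain 1 of 33 above and 16 below. By size, 85 genes were higher and 64 lower of 6573 in frontal cortex microglia, and 64 and 164 of 6605 in midbrain microglia. In frontal cortex endothelial cells (75 higher, 71 lower of 6788) Ptgs2 was at 2.10, and the flow-responsive gene Klf2 was lower (1757 against 4095 CPM, -1.22), as was Apold1 (-1.97). The interferon median was 0.37 in endothelial cells of frontal cortex and 0.20 in those of midbrain. In these, 16 of 34 lists lay above the range and 2 below in frontal cortex, and 4 of 33 above and 8 below in midbrain.

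The list of thyroid hormone and circadian genes was also low outside astrocytes. It had medians of -0.35 and -0.52 in microglia of frontal cortex and midbrain and -0.56 and -0.72 in endothelial cells, all below the random range, but lay within it in midbrain astrocytes (-0.06). The median of immediate early genes was below the range in endothelial cells of frontal cortex (-0.76) and midbrain (-0.31) and in microglia (-0.28 and -0.08). Most members were lower in frontal cortex microglia, while in midbrain microglia they went both ways. In microglia Fosb (0.60 in frontal cortex, 0.94 in midbrain), Fos (0.54 and 0.70) and Klf4 (0.32 and 0.81) were higher. Ier3 (-0.51 and -0.60), Ccl3 (-0.47 and -0.64), Ier2 (-0.34 and -0.24) and Btg2 (-0.29 and -0.20) were lower. The members named here were picked after their values were seen. The clock activator gene Arntl was higher in transgenic endothelial cells (1.18 in frontal cortex, 1.29 in midbrain) and astrocytes (0.38 and 0.55). Its target Per1 was lower in endothelial cells (-1.52 and -0.93) and astrocytes (-1.10 and -0.35), and Ciart was lower in astrocytes (-0.68 and -0.77), while Cry1 was higher in astrocytes (0.74 and 0.43). The labels give no time of collection.

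RNA of other types differed between libraries. Astrocyte identity genes had a median log2 ratio of 1.03 in frontal cortex microglia, 0.97 in frontal cortex endothelial cells, -1.18 in midbrain microglia and 0.13 in midbrain endothelial cells. The pan-reactive median in frontal cortex endothelial cells was 0.70. Hbb-bs, a haemoglobin gene, was found after thinning in 38.9% of transgenic and 2.42% of wildtype astrocytes of frontal cortex, in 50.4% and 4.49% of microglia and in 40.8% and 4.37% of endothelial cells.

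A hypothesis is that the frontal cortex difference is shared by astrocytes of telencephalic character in the midbrain dissection, since pan-reactive genes were higher in midbrain cluster 10. The genes higher in frontal cortex, without the pan-reactive list, were set against the same genes in midbrain clusters 1, 3 and 5. Their median was 0.66 in cluster 10, with 231 of 254 above 0, and 0.11 in the other clusters, with 167 above 0, a difference of 0.54. This lay between the bounds set for it, 0.58 for the hypothesis and 0.26 against it, so the test left it undecided. The 200 genes lower in frontal cortex had medians of -0.42 and -0.17, a difference of -0.25, and all 10144 genes measured had a median of 0.03 in cluster 10, with 5370 above 0. Cluster 10 was 106 transgenic and 284 wildtype cells of 1 library each.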
